A study of Homo sapiens with 18 samples.

How the data were processed

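Total RNA from 18 human bladder tissue samples was hybridised to 1-colour oligonucleotide arrays, 10 samples from urothelial carcinoma and 8 from normal bladder. Per the labels' protocols, RNA was extracted with Trizol, purified with Qiagen reagents, and detected through biotin with a streptavidin conjugate. The deposited table holds 1 value per probe and array for 17589 probes. Its values run from 3.20 to 15.11 and were read as log2 intensities, a scale inferred from this range because neither the deposited table nor the labels state it. Array medians lay between 7.00 and 7.25, so the authors had already brought the arrays to a near-common level. The background correction, probe summary and normalization are not given in the sources used here. The design text states that there were no technical replicates, and each sample was treated as a separate donor's tissue. No label states that the donors were independent, so p-values measure the spread between these samples.

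The platform annotation paired 16614 probes with 1 gene symbol and 0 probes with several. Another 62 probes were array controls and 913 were not named by the annotation. Genes of the Y chromosome and XIST, 28 in all, were left out, and 1 probe was merged where a gene had more than 1, the brighter probe being kept. This left 16585 genes. No filter on dim genes was applied in the main comparison. No genome coordinates are given, since the build behind the annotation is not given in the sources used here. The number of arrays, not a read depth, limits the precision.

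Tumours were compared with normals by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a variance trend, and all differences are tumour minus normal on the log2 scale. Adjusted p-values follow Benjamini and Hochberg over the 16585 genes, with a threshold of 0.05. Exact two-sided permutation tests over all 43758 splits of the 18 arrays were run for the Aurora kinases, the list scores and the RNA quality measures. The smallest p they allow is 2.29e-05. Leaving out normal replicate 1 leaves 19448 splits.

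Before the data were examined, 31 gene lists were fixed from general knowledge, 12 primary and 19 context lists, with 740 entries. Of these entries 655 were measured, 11 of them after updating an old symbol through the gene table of assembly GRCh38.p14. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over the 31 lists. The same test with an estimated correlation, and limma's fry, were alternatives. A list score is the mean over a list's genes of each gene's log2 value minus its mean over the arrays. Genes were named by a rule fixed at the same time: the 3 Aurora kinases, the 5 largest differences each way among passing genes, the 2 largest passing members of each primary list (or the members of smallest p where fewer passed), and the largest passing member of each context list. The member that this rule names in the DNA repair list is not reported here.

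Correlations of AURKA with 4 list scores were planned within tumours and within normals, 8 relations in all, and p-values were adjusted over all 8. Permutation p-values used 100000 resamples for the 10 tumours. Among the normals AURKA fell into separate clusters of fewer than 6 samples, so no pooled correlation is given for that group, although its 4 relations were computed and entered the adjustment. Correlations were computed with numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

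RNA quality was read as the 3′ minus 5′ log2 level of the GAPDH and beta-actin control probes. Bounds of 1 and 2 on the actin measure, set after seeing it, took in 11 arrays (6 tumours, 5 normals), called the actin range here. Outside it lay 4 tumours, normal replicates 7 and 8, and normal replicate 1. Within the range the tumours read 1.42 to 1.75 and the normals 1.22 to 1.36, and outside it the tumours read 0.25 to 0.45 and normal replicates 7 and 8 read 0.68 to 0.69. The groups thus do not overlap on this measure on either side of the bounds, and comparisons within the range do not separate group from a batch that each group may have had of its own. The labels give no scan date or slide. Permutation p-values of list scores were adjusted over the 31 lists with all arrays, and for the red blood cell score also without normal replicate 1. In the other alternatives they were adjusted over the 12 primary lists.

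Alternatives fixed before the data were examined were quantile normalization, subtraction of array medians, leaving out the dimmest 25 percent of genes, eBayes without trend or with robust estimation, array weights, a Welch test per gene, the GAPDH 3′ minus 5′ level as a covariate, the smooth muscle score as a covariate, and leaving out each sample in turn. Alternatives for a linear table had nothing to act on. Those for several probes per gene could have acted only where the 1 probe was merged, and were not run. Chosen after seeing the data were the comparison within the actin range, quantile normalization without normal replicate 1, and the smooth muscle covariate without normal replicate 1.

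The limma steps were tested on simulated data with known changes in the same 16585 genes. With all 18 arrays, 5.97 percent of genes changed by 0.5 on the log2 scale were recovered, 35.8 percent of those changed by 1 and 86.4 percent of those changed by 2. Without normal replicate 1 these shares were 20.9, 59.7 and 92.4 percent. False calls made up 3.41 percent of all calls with the 18 arrays and 4.17 percent without normal replicate 1. The simulated noise was independent between genes, with the same SD in both groups and no outlying array. These shares may therefore not carry over to the real data.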

Results

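Gene expression was measured on 18 arrays, 10 of urothelial carcinoma and 8 of normal bladder tissue. The series concerns an inhibitor of Aurora kinase A, a mitotic kinase, and the human tissues ask which genes, the Aurora kinases first, differ between carcinoma and normal bladder. The inhibitor experiments themselves are not analysed here. Samples are named by the replicate numbers of the labels, 18 to 27 for tumours and 1 to 8 for normals.

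The arrays other than normal replicate 1 resembled one another. Spearman correlations lay between 0.855 and 0.937 for pairs of tumours, and between 0.903 and 0.983 for pairs of the other 7 normals. Pairs of a tumour and 1 of these normals lay between 0.827 and 0.939. Normal replicate 1 correlated with the other arrays at 0.416 to 0.501. Its values had an SD of 1.23, against 2.04 to 2.20 on the other arrays, and its bioB hybridisation spikes read 13.64, against 7.8 to 9.34. Its GAPDH 3′ minus 5′ level was 3.74, and no other array exceeded 1.54. Between the groups the GAPDH 3′ minus 5′ level was 0.42 ± 0.46 (SD, n = 10) in tumours and 0.78 ± 1.21 (SD, n = 8) in normals (exact permutation p = 0.511, two-sided). Without normal replicate 1 the normals' level was 0.36 ± 0.20 (SD, n = 7; exact permutation p = 0.805). On the beta-actin 3′ minus 5′ measure 6 tumours (1.42 to 1.75) and 5 normals (1.22 to 1.36) fell in 1 range, called the actin range, within which the groups did not overlap, so a batch and the group cannot be told apart by it. Because of normal replicate 1 the counts, the Aurora kinases and the primary lists are also given without it.

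**Figure D1:**
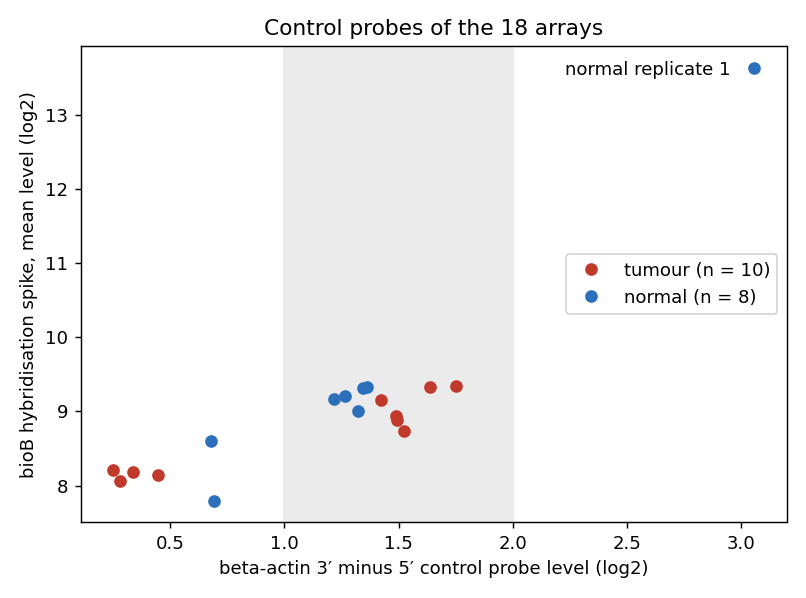
Mean log2 level of the bioB hybridisation spikes against the log2 3′ minus 5′ level of the beta-actin control probes, 1 point per array, for 10 tumours and 8 normals. Normal replicate 1 lies apart at 13.64 and 3.06, and the grey band marks the 11 arrays between 1 and 2.

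AURKA, which encodes the kinase of centrosome maturation and spindle assembly, was higher in carcinoma, at 8.86 ± 0.61 (SD, n = 10) against 6.36 ± 1.38 (SD, n = 8) in normal bladder. The log2 difference was 2.50 (SE 0.45, limma adjusted p = 0.00187), or 5.64-fold, and 9 of 10 tumours lay above the highest normal. AURKB, the kinase of the chromosomal passenger complex, was higher by 2.73 (SE 0.41, limma adjusted p = 0.00058), or 6.62-fold, also with 9 of 10 tumours above the highest normal. AURKC, best known from germ cells, read 6.50 ± 0.27 (SD, n = 10) and 6.61 ± 1.03 (SD, n = 8), a log2 difference of -0.11 that did not pass (limma adjusted p = 0.903). Exact permutation p-values were 0.000137 for AURKA, 4.57e-05 for AURKB and 0.922 for AURKC. Leaving out normal replicate 1 gave log2 differences of 2.76 for AURKA, 2.61 for AURKB and 0.25 for AURKC, the last with its sign turned and an adjusted p of 0.254. Within the actin range they were 2.64, 2.55 and 0.33. With the smooth muscle score as a covariate the AURKA difference was 1.53 (SE 0.45) and no longer passed (limma adjusted p = 0.108), while AURKB stood at 2.15 (adjusted p = 0.0465). Leaving out normal replicate 1 as well, that covariate left AURKA at 1.83 (adjusted p = 0.0718) and AURKB at 1.81 (adjusted p = 0.0878).

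**Figure D2:**
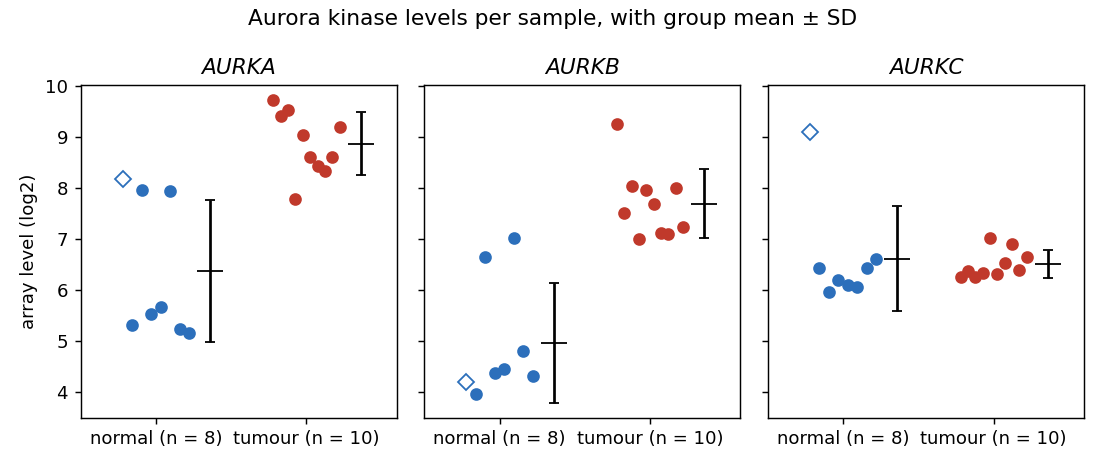
Array level (log2) of AURKA, AURKB and AURKC in each normal (n = 8) and tumour (n = 10) sample, with the group mean ± SD at the right of each set of points; the open diamond is normal replicate 1. AURKA averaged 8.86 in tumours and 6.36 in normals, and AURKC differed by -0.11, which did not pass and turned to 0.25 without normal replicate 1.

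The normals were not uniform in AURKA. Normal replicates 1, 3 and 6 read 8.18, 7.95 and 7.94, and the other 5 read 5.14 to 5.65. Tumours ranged from 7.78 to 9.72. Normal replicate 1 is the outlying array, and its AURKA value may not be comparable. With all arrays its score for mitotic kinases, spindle and cytokinesis was -0.58. That score was 0.30 and 0.37 in normal replicates 3 and 6, and -2.05 to -1.76 in the other 5. Across the 10 tumours AURKA followed the score of the spindle checkpoint and kinetochore list, which does not contain it (Pearson r = 0.886, permutation p = 0.00051, adjusted p = 0.00408 over 8 relations; Spearman rho = 0.915, permutation p = 0.00044). Without the 2 tumours farthest from the median r was 0.746 (n = 8) and no longer passed (exact permutation, adjusted p = 0.0652). Among the 6 tumours of the actin range r was 0.922 (exact permutation p = 0.0236) and rho 0.657 (exact permutation p = 0.175), and the other 4 tumours are too few for a correlation. The relation of AURKA to the smooth muscle score (r = -0.485, permutation p = 0.156; rho = -0.442, permutation p = 0.203) did not pass. Nor did those to the basal and squamous score (r = 0.444, permutation p = 0.196; rho = 0.406, permutation p = 0.247) and to the T and NK cell score (r = 0.492, permutation p = 0.149; rho = 0.406, permutation p = 0.247). Their adjusted p-values for r were 0.25, 0.261 and 0.25, and within the actin range r was -0.394, 0.367 and 0.490, with exact permutation p-values of 0.514, 0.540 and 0.346.

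Across all genes, carcinoma had 679 genes higher and 623 lower than normal bladder, 1302 of 16585 (limma, Benjamini-Hochberg adjusted). Of these, 385 were at least 2-fold higher and 518 at least 2-fold lower. The largest increases were in cell division genes. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was higher by 3.92 (SE 0.47, limma adjusted p = 0.000126), with all 10 tumours above the highest normal. TOP2A, a DNA topoisomerase, was higher by 3.70, CDC20, an activator of the anaphase-promoting complex, by 3.51, CCNB2, a mitotic cyclin, by 3.25, and CEP55, a cytokinesis protein, by 3.22. Among the largest decreases, ADH1B, an alcohol dehydrogenase, fell by 5.40 (SE 0.78, limma adjusted p = 0.000441), and the transporter gene ABCA8 fell by 4.30. OGN, a small leucine-rich proteoglycan, differed by -4.28, the matrix gene ABI3BP by -4.0 and PDK4, a pyruvate dehydrogenase kinase, by -3.89, all passing.

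Without normal replicate 1, 2284 genes passed, 1247 higher and 1037 lower, and 672 of the higher and 608 of the lower genes were shared with the comparison of all arrays. Within the actin range 6337 genes passed, 4275 higher and 2062 lower, with 603 and 565 shared. No gene called in either was called in the opposite direction with all arrays. The median of all genes shifted to 0.11 without normal replicate 1 and to 0.17 within the range.

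The 4 cell cycle lists were higher in carcinoma. Of 38 measured genes for mitotic kinases, spindle and cytokinesis, 31 rose, 0 fell and 7 did not pass, and adjusted over the list alone 36 rose. The mean log2 difference was 2.05 (limma camera adjusted p = 9.28e-31; adjusted p = 0.0691 with an estimated correlation), and UBE2C and CEP55 led the list. Of 30 spindle checkpoint and kinetochore genes, 19 rose and 0 fell (23 rose adjusted over the list alone), with a mean of 1.53 (camera adjusted p = 2.99e-18; adjusted p = 0.069 with an estimated correlation). CDC20 and the checkpoint kinase TTK, higher by 3.18, were its largest. Of 18 G2/M cyclins and regulators, 13 rose and 0 fell (17 rose and 1 fell adjusted over the list alone), with a mean of 1.83 (camera adjusted p = 3.08e-14; adjusted p = 0.069 with an estimated correlation). Of 37 DNA replication genes, 27 rose and 0 fell (35 rose adjusted over the list alone), with a mean of 1.53 (camera adjusted p = 2.87e-29; adjusted p = 0.0569 with an estimated correlation). In that list RRM2, a ribonucleotide reductase subunit, was higher by 3.19 and DTL, an adaptor of a replication-linked ubiquitin ligase, by 2.65. Without normal replicate 1 the means of the 4 lists, in this order, were 2.13, 1.55, 1.90 and 1.53, and within the actin range 1.96, 1.48, 1.85 and 1.36. With the smooth muscle covariate the spindle checkpoint mean was 0.99 and the G2/M mean 1.18, both still passing with camera (adjusted p = 6.56e-12 and 7.16e-09).

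The score of the mitotic kinase list was 0.91 ± 0.58 (SD, n = 10) in tumours and -1.14 ± 1.01 (SD, n = 8) in normals (exact permutation p = 0.000114). The scores of the other primary lists gave exact permutation p-values of 0.000229 for spindle checkpoint, 0.000114 for G2/M, 0.000114 for DNA replication, 0.00939 for smooth muscle, 0.00539 for immediate early genes and 0.00226 for T and NK cells, and these 6, like the mitotic kinase score, passed after adjustment. Those of urothelial differentiation (0.672), basal and squamous epithelium (0.173), fibroblasts (0.0831), interferon response (0.668) and macrophages (0.201) did not pass. Scored without normal replicate 1, normal replicates 3 and 6 read 0.26 and 0.34, the other 5 normals -2.08 to -1.80, and the tumours -0.28 to 1.94. Smooth muscle scores moved with the groups too, and of the 7 normals those of replicates 3 and 6 were lowest, at 0.11 and -0.22.

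**Figure D3:**
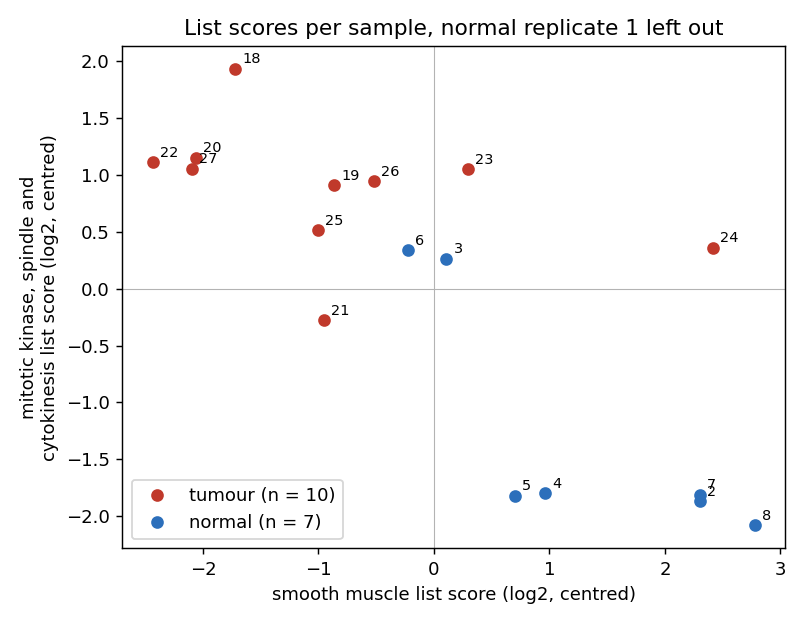
Score of the mitotic kinase, spindle and cytokinesis list against that of the smooth muscle list (both log2, centred over the arrays plotted), 1 numbered point per sample, for 10 tumours and 7 normals, normal replicate 1 left out. Normal replicates 3 and 6 lie at 0.26 and 0.34 on the mitotic axis, among the tumours.

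Smooth muscle genes were lower in carcinoma. Of 22 measured genes 10 fell and 0 rose, 15 fell adjusted over the list alone, and the mean was -1.96 (camera adjusted p = 2.5e-12; adjusted p = 0.169 with an estimated correlation). MYH11, the smooth muscle myosin heavy chain, fell by 3.16 and SYNM, an intermediate filament protein, by 3.14. The mean was -2.17 without normal replicate 1 and -2.46 within the actin range. Tumours spread widely in this score, and tumour replicate 24 stood at 2.41 against -2.44 in tumour replicate 22.

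Of 26 fibroblast and connective tissue genes, 8 fell and 0 rose (10 fell adjusted over the list alone). Its mean was -0.91 and the median -0.35 (camera adjusted p = 0.000166; adjusted p = 0.373 with an estimated correlation). OGN and the complement gene C7, which fell by 3.73, were its largest. The mean was -1.19 with normal replicate 1 left out and -2.01 within the actin range.

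Immediate early genes, which respond to stimulation and to tissue handling, were lower in carcinoma, with 10 of 21 falling and 0 rising (15 fell adjusted over the list alone). The mean was -1.42 (camera adjusted p = 7.64e-11; adjusted p = 0.169 with an estimated correlation), and the transcription factor genes NR4A2 and FOSB fell by 2.80 and 2.65. The mean went to -1.65 when normal replicate 1 was left out and was -2.16 within the actin range.

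Urothelial differentiation genes showed no shared shift between the groups. Of 23 measured, 1 fell and 22 did not pass, the same count adjusted over the list alone, with a mean of -0.25 (camera adjusted p = 0.683; adjusted p = 0.902 with an estimated correlation). The gene that fell was UPK1A, a uroplakin of the luminal membrane, with a difference of -3.84 (SE 0.93, limma adjusted p = 0.0137). CDH1, the epithelial cadherin, differed by 1.03 and did not pass (limma adjusted p = 0.113). The directional sign of fry for this list was up while its mean and median were below 0. That mean was -0.54 without normal replicate 1 and -0.42 within the actin range. With all arrays the list's score ran from -2.17 to 1.44 among the tumours. Among the normals other than replicate 1 it ran from -0.006 to 1.22.

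Of 19 basal and squamous genes, 1 rose and 18 did not pass, the same count adjusted over the list alone. KRT14, a basal keratin, was higher by 3.06 (SE 0.79, limma adjusted p = 0.0195), and the cadherin gene CDH3 differed by 1.44 (limma adjusted p = 0.104). The list's mean of 0.71 passed with camera (adjusted p = 0.0331; adjusted p = 0.441 with an estimated correlation). It did not pass without normal replicate 1 (0.68, camera adjusted p = 0.307) or within the actin range (0.66, camera adjusted p = 0.71).

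T and NK cell genes were lower in carcinoma, with 12 of 26 falling and 0 rising (17 fell adjusted over the list alone). The mean was -0.98 (camera adjusted p = 1.04e-13; adjusted p = 0.0888 with an estimated correlation). KLRB1, a lectin-like receptor of NK and some T cells, fell by 2.17 (SE 0.26, limma adjusted p = 0.000126), and all 10 tumours lay below the lowest normal. CD2, a T cell adhesion receptor, fell by 1.74 with all arrays, a call lost without normal replicates 4, 5 or 7 (-1.62, -1.57 and -1.59). With normal replicate 1 left out the mean was -1.01, and within the actin range -0.95.

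Of 19 macrophage and monocyte genes, 1 rose and 0 fell (1 rose and 5 fell adjusted over the list alone), with a mean of -0.44 (camera adjusted p = 0.00165; adjusted p = 0.318 with an estimated correlation). The riser, SPP1, encodes osteopontin, which tumour cells also make. It was higher by 2.56 with all arrays, and by 1.79 within the actin range, where it did not pass (limma adjusted p = 0.11). AIF1 differed by -0.66 (limma adjusted p = 0.0567). The list's mean was -0.59 without normal replicate 1, -0.29 without tumour replicate 22 and -0.86 within the range.

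Of 25 interferon response genes, 1 rose and 24 did not pass, the same count adjusted over the list alone, with a mean of 0.16 (camera adjusted p = 0.485; adjusted p = 0.902 with an estimated correlation). ISG15, an interferon-induced ubiquitin-like protein, was higher by 1.53 (SE 0.37, limma adjusted p = 0.0144), and IFI6 differed by 1.21 (limma adjusted p = 0.08). The list's mean turned to -0.03 without normal replicate 1 and to -0.12 within the actin range.

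**Figure D4:**
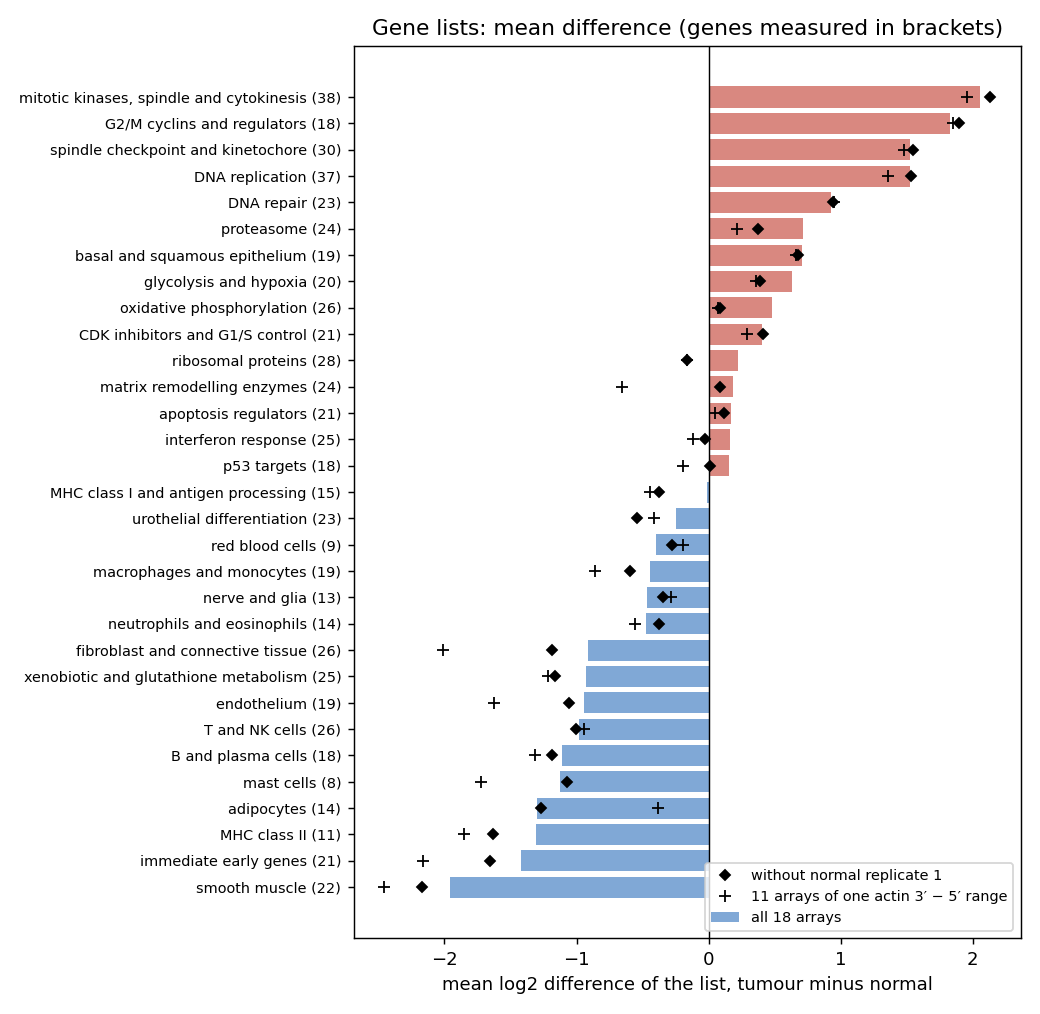
Mean log2 difference (tumour minus normal) of each of the 31 gene lists, with the number of genes measured in brackets; bars give all 18 arrays, diamonds 17 arrays without normal replicate 1, and crosses the 11 arrays of the actin range. Mitotic kinases stand highest at 2.05 and smooth muscle lowest at -1.96 with all arrays.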

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

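The tests of explanations in this part were chosen after the results had been seen. In 154 groups examined, 30 held a sample whose gap to its nearest neighbour was large against the group's range. Of the 30, 20 were normal replicate 1. For normally distributed values chance alone would give about 7.7. The groups share arrays and genes, so an excess over 7.7 was not tested.

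In normal replicate 1 the list scores far from the other normals were those of urothelial differentiation (-1.94), fibroblast and connective tissue (-1.41), macrophages and monocytes (-0.81), p53 targets (-1.12), MHC class II (-1.56), MHC class I and antigen processing (-2.50), glycolysis and hypoxia (-2.05), oxidative phosphorylation (-3.06), the proteasome (-2.75), ribosomal proteins (-2.80) and xenobiotic and glutathione metabolism (-1.12). Single genes far from the other normals were AURKC at 9.10, ADH1B at 5.25, CDH1 at 6.77, CD2 at 6.30, TPI1 at 10.15 and PSMB2 at 8.11. Its GAPDH 3′ minus 5′ level was 3.74, its actin 3′ minus 5′ level 3.06 and its bioB spike level 13.64.

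That array stands apart from the other 17 as a whole. A mislabelled bladder sample on a sound array is argued against, since its highest correlation with any array, 0.501, lay below 0.827, the lowest between any pair of the others. Little sample RNA on the array is a candidate explanation: the bioB spikes, added in fixed amount, exceeded the brightest other array by 4.30 on the log2 scale, and its actin 3′ level of 10.98 lay below the 14.14 to 14.64 of the others. Degraded RNA may also contribute, with the GAPDH 3′ minus 5′ level of 3.74 against at most 1.54 elsewhere. These explanations can hold together, and no biological explanation was tested.

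Among the tumours, replicate 24 stood apart in the score of B and plasma cells (0.60) and in CDH19 (5.05), and replicate 23 in ADH1B (8.86) and NR4A2 (10.60). Tumour replicate 18 stood apart in AURKB (9.26) and CXCR2 (6.99). Tumour replicate 21 was low in CEP55 (6.18) and high in the GAPDH 3′ minus 5′ level (1.54), and replicate 19 was high in TPI1 (14.26). Normal replicate 8 had an adipocyte score of 3.81.

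Among 913 probes that the annotation does not name, which no comparison above uses, 22 were higher and 26 lower in tumours in the same limma test.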

How the results depend on the processing

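Chosen after seeing the data were the comparison within the actin range, quantile normalization without normal replicate 1, and the smooth muscle covariate without normal replicate 1. No paired analysis was possible because the replicate numbers of tumours (18 to 27) and normals (1 to 8) share none. Subtracting array medians, eBayes without trend and robust eBayes changed no direction or call among the 19 main results and the 59 named genes and context lists. The cause of the changes that follow was not tested. Dim signal limits genes near the background, for which the table gives no detection call.

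The count of 1302 genes (679 higher, 623 lower) became 2298 (1254, 1044) with the GAPDH covariate, 5529 (3406, 2123) with array weights, 2252 (1154, 1098) with quantile normalization without normal replicate 1, 6337 (4275, 2062) within the actin range, 120 (47, 73) with the smooth muscle covariate, and 119 (53, 66) with that covariate and without normal replicate 1. The count of 903 with at least a 2-fold difference became 1743 with array weights, 2265 within the actin range, 119 with the smooth muscle covariate and 103 with it and without normal replicate 1. Leaving out 1 sample gave 862 to 2284 genes (434 to 1247 higher, 428 to 1037 lower) and 684 to 1111 with at least a 2-fold difference. The 862 and 434 came without normal replicate 4, the 2284, 1247 and 1037 without normal replicate 1, and 450 higher genes were found without normal replicate 5.

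AURKA was 1.53 (limma adjusted p = 0.108) with the smooth muscle covariate and 1.83 (adjusted p = 0.0718) with it and without normal replicate 1, where AURKB was 1.81 (adjusted p = 0.0878). AURKC, at -0.11 with all arrays, turned to 0.14 with the GAPDH covariate, 0.30 with array weights, 0.25 with quantile normalization without normal replicate 1, 0.32 with the smooth muscle covariate without it, and 0.33 within the actin range. Leaving out 1 sample gave 2.32 to 2.76 for AURKA, 2.55 to 3.02 for AURKB and -0.20 to 0.25 for AURKC, the last value without normal replicate 1.

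With an estimated correlation the camera calls ended for spindle checkpoint (1.53, adjusted p = 0.069), mitotic kinases (2.05, 0.0691), G2/M (1.83, 0.069), DNA replication (1.53, 0.0569), basal and squamous (0.71, 0.441), smooth muscle (-1.96, 0.169), fibroblast (-0.91, 0.373), immediate early (-1.42, 0.169), T and NK (-0.98, 0.0888) and macrophage lists (-0.44, 0.318). With fry the calls ended for basal and squamous (0.71, adjusted p = 0.171), fibroblast (-0.91, 0.142) and macrophage lists (-0.44, 0.104), and among context lists for neutrophils (-0.47, 0.0689), nerve and glia (-0.46, 0.103), adipocytes (-1.30, 0.0636), oxidative phosphorylation (0.48, 0.259), the proteasome (0.71, 0.082) and xenobiotic metabolism (-0.93, 0.121). The sign of fry turned for urothelial differentiation (-0.25) and MHC class I (-0.0142). The basal and squamous call also ended with the GAPDH covariate (0.67, camera adjusted p = 0.213), the Welch test (0.71, 0.073), array weights (0.58, 0.501), the dimmest genes left out (0.71, 0.125), quantile normalization without normal replicate 1 (0.67, 0.207) and within the actin range (0.66, 0.71).

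The sign turned for interferon response with the GAPDH covariate (-0.0102), array weights (-0.11), quantile normalization without normal replicate 1 (-0.0427) and within the actin range (-0.12). A turned sign of the mean or of the camera test was found for ribosomal proteins under the same settings in that order (-0.056, -0.158, -0.147, -0.166) and under quantile normalization (0.0305). It was found for matrix remodelling enzymes with the GAPDH covariate (0.0422), array weights (-0.0894) and within the range (-0.65), for p53 targets with array weights (-0.0301), quantile normalization without normal replicate 1 (0.002) and within the range (-0.20), and for apoptosis regulators with array weights (0.11) and within the range (0.0469). Within the range it was also found for red blood cells (-0.19) and oxidative phosphorylation (0.0724). Matrix remodelling enzymes passed as lower within the range (camera adjusted p = 0.00843, but 0.471 with an estimated correlation), where 6 of them fell and 3 rose.

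Leaving out 1 sample gave list means of 1.43 to 1.68 for spindle checkpoint, 1.92 to 2.27 for mitotic kinases, 1.71 to 2 for G2/M, 1.45 to 1.66 for DNA replication, -2.32 to -1.71 for smooth muscle, -1.19 to -0.68 for fibroblast, -1.65 to -1.25 for immediate early, -1.11 to -0.89 for T and NK and -0.59 to -0.29 for macrophage lists, with no camera call lost. The basal and squamous mean ranged from 0.53 to 0.94 and lost its call without tumour replicates 18, 22, 24, 26 or 27 or normal replicates 1, 7 or 8 (0.61, 0.58, 0.67, 0.63, 0.53, 0.68, 0.60 and 0.60). The urothelial mean ranged from -0.54 to -0.0178, and its test turned sign without tumour replicates 18, 19 or 23 or normal replicate 6. The interferon mean ranged from -0.0261 to 0.28, below 0 without normal replicate 1 or tumour replicate 18. The fibroblast score passed the exact permutation test only without normal replicate 1 (-1.19, adjusted p = 0.0329 over the 12 primary lists). Among context lists, MHC class I ranged from -0.37 to 0.0764, ribosomal proteins from -0.16 to 0.29, p53 targets from 0.0088 to 0.20 and matrix remodelling enzymes from 0.0619 to 0.35. The tumour minus normal GAPDH 3′ minus 5′ level of -0.36 ranged from -0.49 to 0.0586, above 0 without normal replicate 1. The correlation of AURKA with the spindle checkpoint score was 0.746 (adjusted p = 0.0652) without the 2 samples farthest from the AURKA median.

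Of the named genes, PSMB2 lost its call without tumour replicates 18, 20 or 27 (1.19, 1.20, 1.11) or normal replicates 4 or 5 (1.23, 1.22). TP53I3 lost it without any one of tumour replicates 18, 20, 21, 22, 24 or 25 or normal replicates 2, 4, 5, 7 or 8 (0.85 to 0.94), and within the actin range (0.54, adjusted p = 0.165). CDH3 passed without tumour replicate 25 (1.78), IFI6 without tumour replicate 21 (1.39), and AIF1 without tumour replicates 19 or 23 or normal replicate 2 (-0.71, -0.75, -0.73). CD2 also lost its call under quantile normalization (-1.58). With the Welch test RRM2, SPP1, CD2, TP53I3, CDH19 and PSMB2 lost theirs (adjusted p = 0.0509, 0.0509, 0.0573, 0.0952, 0.0903 and 0.0764). CDH3 also passed with array weights (adjusted p = 0.0168) and within the actin range (0.038), and IFI6 with array weights (0.0211). AIF1 also passed with the dimmest genes left out (adjusted p = 0.045), array weights (0.00947), the Welch test (0.0396), the GAPDH covariate (0.0417), quantile normalization without normal replicate 1 (0.0427) and within the actin range (0.0371). SPP1 did not pass within the actin range (0.11).

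Among context lists, camera calls ended for CDK inhibitors and G1/S control with the GAPDH covariate, array weights and the dimmest genes left out (adjusted p = 0.0649, 0.159 and 0.0703). They ended for nerve and glia with array weights, the dimmest genes left out and quantile normalization without normal replicate 1 (0.175, 0.115 and 0.0576). They ended for oxidative phosphorylation with the GAPDH covariate, array weights and quantile normalization without normal replicate 1 (0.265, 0.887 and 0.624), and for glycolysis with array weights (0.082). At the preset correlation MHC class I passed with these last 3 settings of oxidative phosphorylation and within the actin range (-0.29, -0.38, -0.37 and -0.44). With array weights the means of adipocytes (-0.77) and the proteasome (0.33) moved by over 1.5 times and still passed.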

Other observations

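The tests of explanations, the criteria for the splits of the samples and the comparison within the actin range were chosen after the results had been seen.

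DNA repair genes rose with the cell cycle lists: 10 of 23 rose and 1 fell (15 rose and 1 fell adjusted over the list alone), with a mean of 0.93 (limma camera adjusted p = 1.15e-09; adjusted p = 0.0569 with an estimated correlation). Of 21 genes for CDK inhibitors and G1/S control, 5 rose and 0 fell (6 rose adjusted over the list alone), with a mean of 0.41 (camera adjusted p = 0.0121; adjusted p = 0.128 with an estimated correlation; 0.0637 at the preset correlation without normal replicate 1). That call also ended within the actin range (0.29, camera adjusted p = 0.577). CCNE1, cyclin E1, was higher by 2.20 in that list, with all 10 tumours above the highest normal. No CDK inhibitor gene of the list was called with all arrays. Glycolysis and hypoxia genes had a mean of 0.63 (camera adjusted p = 0.000462; adjusted p = 0.316 with an estimated correlation), 0.39 without normal replicate 1 and 0.36 within the actin range, where it did not pass (camera adjusted p = 0.347), and 2 of 20 rose, also adjusted over the list alone, among them TPI1 by 1.44. Proteasome genes had a mean of 0.71 (camera adjusted p = 9.26e-07; adjusted p = 0.318 with an estimated correlation), 0.38 without normal replicate 1 and 0.21 within the actin range, where it did not pass (camera adjusted p = 0.71), and 4 of 24 rose (6 adjusted over the list alone), PSMB2 by 1.22 with all arrays. The mean of 26 oxidative phosphorylation genes, 0.48 (camera adjusted p = 0.00165; adjusted p = 0.527 with an estimated correlation), was 0.08 without normal replicate 1 and no longer passed (camera adjusted p = 0.884), and 0 of its genes passed singly or adjusted over the list alone.

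Lists of other cell types were lower in carcinoma. Endothelial genes had a mean of -0.94 (camera adjusted p = 9.25e-08; adjusted p = 0.169 with an estimated correlation), and -1.63 within the actin range (5.96e-12; 0.139), with 4 of 19 falling (7 adjusted over the list alone), EMCN with a difference of -2.29, and -3.59 within the range. B and plasma cell genes had a mean of -1.11 (camera adjusted p = 1.41e-07; adjusted p = 0.0888 with an estimated correlation), 4 of 18 falling (11 adjusted over the list alone), POU2AF1, a B cell transcriptional coactivator, with -3.16. Mast cell genes had a mean of -1.13 (camera adjusted p = 2.45e-05; adjusted p = 0.0888 with an estimated correlation), and -1.72 within the range (1.54e-05; 0.206), with 2 of 8 falling (7 adjusted over the list alone), HPGDS with -1.64. MHC class II genes had a mean of -1.31 (camera adjusted p = 7.64e-05; adjusted p = 0.169 with an estimated correlation), 0 of 11 passing with all arrays (2 fell adjusted over the list alone) and 8 falling without normal replicate 1. Adipocyte genes had a mean of -1.30 (camera adjusted p = 5e-05; adjusted p = 0.265 with an estimated correlation). Their mean was -0.86 without normal replicate 8, and -0.38 with a median of 0.23 within the actin range, where the list did not pass (camera adjusted p = 0.856) and 3 genes rose and 1 fell. With all arrays 1 of 14 fell, also adjusted over the list alone: CFD, which macrophages also express, with -3.87. Xenobiotic and glutathione metabolism had a mean of -0.93 (camera adjusted p = 0.00165; adjusted p = 0.316 with an estimated correlation), 4 of 25 falling, ADH1B the most.

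Neutrophil and eosinophil genes (mean -0.47, camera adjusted p = 0.00559; adjusted p = 0.265 with an estimated correlation) and nerve and glia genes (mean -0.46, camera adjusted p = 0.00899; adjusted p = 0.317 with an estimated correlation) did not pass without normal replicate 1, at adjusted p-values of 0.0523 and 0.0768, or within the actin range, at 0.19 and 0.486. CXCR2 fell by 1.68 in the first list and CDH19 by 1.48 in the second. The lists of p53 targets (mean 0.16, camera adjusted p = 0.338), apoptosis regulators (mean 0.17, camera adjusted p = 0.256), red blood cells (mean -0.40, camera adjusted p = 0.0965), MHC class I and antigen processing (mean -0.01 but median 0.06, camera adjusted p = 0.721), ribosomal proteins (mean 0.22, camera adjusted p = 0.48) and matrix remodelling enzymes (mean 0.18, camera adjusted p = 0.298) did not pass with all arrays. Of the context lists that passed with camera, the scores of neutrophils and eosinophils, oxidative phosphorylation and xenobiotic metabolism did not pass the exact permutation test (adjusted p = 0.0675, 0.163 and 0.0729), while that of red blood cells, which camera did not call, did (0.0418), but not without normal replicate 1 (0.0864). Among the members of the lists that did not pass with camera TP53I3 rose by 0.92, but by 0.54 within the actin range, where it did not pass (limma adjusted p = 0.165). Of 24 matrix remodelling enzymes 2 rose and 1 fell, ADAMTS1 by 3.33. With normal replicate 1 left out the MHC class I list stood at -0.37 and passed (camera adjusted p = 0.000741), and the ribosomal list turned to -0.16 and passed (camera adjusted p = 0.000741). Neither passed there with an estimated correlation (camera adjusted p = 0.26 for each).

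Other splits of the samples rarely gave as many genes. Among 100 splits of the 18 arrays, the real one included, 1 gave as many genes as the 1302 called, and the highest other gave 8. For genes with at least a 2-fold difference 1 of 100 reached the real 903, and the highest other gave 8. A chance split of the arrays is argued against for both counts, but 100 splits cannot resolve a share below 1 of 100. The splits do not separate the group from a batch that each group had of its own. Leaving out normal replicate 1, 2 of 100 splits reached the real 2284, and the highest other gave 3128, above the real count. That split sets 6 of the 7 normals and tumour replicate 24 against the rest, so it differs from the real one by an exchange of 1 normal for 1 tumour. It points to a structure of the samples that the labels do not capture in full. Of the 7 arrays on its smaller side, 5 were among the 7 highest smooth muscle scores. The 7 normals of the real grouping hold as many of these scores, so the count does not set that split apart. Smooth muscle content as the source of that structure was not tested. The actin range set against the other arrays called 4 genes, in a fit that left out the group and so says little about a batch.

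The mitotic list was higher in tumours. An array batch that the actin measure follows is argued against as the whole cause: tumours lie above normals on that measure within the actin range and below them outside it, yet the mitotic difference was 1.96 within (exact permutation p = 0.00866) and 2.67 outside (4 tumours, 2 normals, not tested), and 2.26 (SE 0.40) without normal replicate 1 with range and actin level as covariates. A batch that each group had of its own cannot be told apart from the group, because the groups do not overlap on the measure on either side. Less smooth muscle is argued against as the whole cause of the list's difference, as far as the score measures muscle. With the smooth muscle score as a covariate the difference was 1.37 (SE 0.40), against 2.05 without. A part played by muscle stays open, since of the 7 normals replicates 3 and 6 were lowest in that score and highest in the mitotic one. For single genes the rule was another one, a call adjusted over 16585 genes, and by it the matter stays open. AURKA went from 2.50 (SE 0.45) to 1.53 (SE 0.45) and lost its call as its estimate shrank. AURKB lost its own once normal replicate 1 was also left out (1.81, SE 0.50). The list was judged by its difference against its SE alone, so these verdicts do not rank AURKA below the list. More epithelium is argued against as the whole cause, since the mitotic score rose by 1.37 more than that of 7 pan-epithelial genes (exact permutation p = 0.0471; 1.88 without normal replicate 1, exact permutation p = 0.00231). The pan-epithelial score itself was higher by 0.68 (exact permutation p = 0.148). It was higher by 0.255 without normal replicate 1 (exact permutation p = 0.38), so a share from epithelium stays open. Higher proliferation in carcinoma stays open beside a batch of each group's own and a share from tissue composition, as a hypothesis found and tested on the same data.

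Normal replicates 3 and 6 carried mitotic scores of 0.26 and 0.34. An array batch marked by the actin range is argued against, since the highest other normal of that range stood at -1.80. A finer batch within the range was not tested, as the labels give no scan date or slide. Tumour cells or tumour RNA in these samples cannot be told apart from another origin. Set against the other normals without normal replicate 1, the cell cycle genes of replicate 3 would need a 45.1 percent share of average tumour RNA and other tumour-high genes 20.1 percent, a gap of 25 points (95 percent bootstrap interval 15.8 to 31.8 over 1000 draws), and in replicate 6 the gap was 42.3 points. For replicates 3 and 6 that reference held the other of the pair, and for the other 5 normals it held both, which lowers the cell cycle shares. In the other 5 normals the gaps were -3.5, -1 and -2.3 points in replicates 2, 4 and 5, of the same actin range, and -15.9 and -23.6 in replicates 7 and 8, a spread between samples that the interval over genes does not cover. The profile of any admixed tumour is unknown, which keeps this open, and proliferating urothelium was not tested.

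A hypothesis that tumours differ more from one another in epithelial state than normals do was tested without normal replicate 1. Most genes spread more among tumours, with a median log2 ratio of tumour SD to normal SD of 0.55 over all genes. The mean log2 ratio of urothelial differentiation genes was 1.11, against a median of 0.80 over 10000 random lists matched on mean level (percentile 97.65). That value goes the way of the hypothesis but does not decide it. The list's genes are correlated (estimated correlation 0.441), while random lists draw unrelated genes and so spread too little. The cut-off for the percentile was also set after the result. For basal and squamous genes the mean ratio was 0.79 against 0.62 (percentile 82.76), which leaves the matter open.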
